A study of Mus musculus with 15 samples.

How the data were processed

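Promoter-capture Hi-C libraries were made from hippocampal nuclei sorted for the neuronal protein NeuN and the yellow fluorescent label. Per the labels, tissue of 10 to 12 mice was pooled to reach 10000 nuclei per condition, nuclei were fixed with 2% paraformaldehyde for 10 min and digested with HindIII, and the libraries were amplified in 17 PCR cycles and captured with 10000 RNA baits for 5000 promoters. Mice received 4-hydroxytamoxifen 1 h before contextual fear conditioning. The design states 3 to 5 biological replicates and the protocol 3 to 4. The treatment labels give a collection day that runs from 0 to 14 with the order of the samples and state no recall for every sample, which conflicts with the protocol, so they were not used and groups were taken from the sample titles.

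The deposited values are the authors' interaction score for each promoter and fragment in each of 15 libraries, per the file headers, on genome build mm9. The program that made the score, the aligner, the filters and any normalization are not given in the sources used here. The scores are whole numbers of 2 or more, and a dot stands where no score is listed. Whole numbers with library sums from 3097 to 8218430 are also what read numbers per interaction would look like, so a difference in score can carry a difference in depth between libraries. The bait positions are not in the table used here, so neither the distance from promoter to fragment nor contacts between baited fragments could be computed. Of the promoter names, 4280 of 4429 matched a gene symbol of the reference, 144 a synonym and 5 neither. Names are printed as deposited. Of 2586 fragments listed with several promoters, 2585 had identical scores in all their listings, so such a score cannot be assigned to a single promoter. For 8 promoters, fragments on more than 1 chromosome were listed.

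Groups were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) with a robust empirical Bayes step and a variance trend, on asinh(score) with 0 for no score and no filter. All 15 libraries shared a single fit, and the Benjamini-Hochberg adjusted p had to be under 0.05. The unit was the listing of a promoter with a fragment, 36353 in all. Gene lists were tested with camera of the same package on the mean asinh score of each promoter over its listed fragments, with a preset correlation of 0.01 and also with an estimated correlation. The 20 lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. Limma on the mean score of each promoter and on its number of called interactions was added afterwards. An interaction was called at a score of 5 or more, and in a group if it was called in any library of the group. Descriptive values, permutations and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

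The genes named in each of the first 3 comparisons were the 6 fragments with the largest rise and the 6 with the largest fall in mean asinh score among those called in either group, with 1 per promoter; the 5 promoters with the largest gain and the 5 with the largest loss in called interactions; and up to 2 genes in each direction from each list described. For the other 3 comparisons, the 3 promoters with the largest gain and loss were named. Arc was named in any case, and predicted genes, microRNAs, olfactory receptors and clone names were skipped. Some genes that the rule selects are left out of the text and of the counts of named results. Promoters that passed the test on mean scores, and those of fragments scored in a single group, were named after their values were seen.

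Libraries of a group that shared at least 40% of the fragments of the smaller library were joined into a library set, a rule chosen after the sharing was seen. With the set as a random block, the correlation within sets was 0.974. The method was tested on simulated data in which 200 listings were given a change between groups. With the spread of scores as found in the table, limma recovered 0 of the 200 in each comparison. At a score of 10000 in every library of a group, it recovered 200 of 200 with independent libraries in 5 comparisons and 0 in Reactivated against Late. With libraries of a set sharing their fragments, it recovered 193, 200, 200, 199, 171 and 200 in Early against Basal, Late against Early, Reactivated against Late, Late against Basal, Reactivated against Basal and Reactivated against Early. Without the variance trend and with such sharing, it recovered, at the spread found in the table, 110, 122, 108, 91, 105 and 79 in the same order, and it called 262, 139, 152, 417, 274 and 10 listings with no change added. Camera found a shift of 1 on the asinh scale in a simulated list of 30 promoters in all 6 comparisons. For a list of 30 other promoters, left unshifted in the same simulated data, the unadjusted camera p was 0.0482 in Early against Basal. It was 0.179 to 0.845 in the other comparisons. The correlations estimated for the gene lists in the data were 0.20 to 0.66. Whether camera finds such a shift at these correlations was not tested.

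Alternatives were the threshold for a call (3, 7 and 10), equal numbers of calls per group, log2(score + 1), a filter on low scores and quantile normalization. Further ones were other summaries per promoter, leaving out promoters listed on more than 1 chromosome, the replicate number as a block, and each library left out. Chosen after seeing the data were each library set as its mean or as a random block, no variance trend, leaving out Reactivated libraries 1 and 2, each fragment counted a single time, fragments listed with 1 promoter, and scores scaled to the same total in each library. Read depth per library is not given in the sources used here, so no counting intervals were computed.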

Results

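Promoter-capture Hi-C, a method that joins and sequences DNA fragments lying close together in the nucleus and enriches those joined to chosen promoters, was carried out on sorted hippocampal neuronal nuclei of mice. The mouse line makes a yellow fluorescent protein in cells whose Arc promoter is active while 4-hydroxytamoxifen is present, so that cells active during contextual fear conditioning are labelled. The 15 libraries fall into 4 groups: Basal with 3 libraries, and Early, Late and Reactivated with 4 libraries each. The design names encoding, consolidation and recall of a memory as its stages, and the protocol gives collection 1.5 to 2 h after the task or 5 days after conditioning, the latter with or without renewed exposure to the cue. The labels do not state which group was collected at which interval, nor how the Basal group was treated, so the groups are named here as in the titles. Each deposited value is the interaction score of a library for a pair of a promoter and a HindIII fragment, with positions on mouse genome build mm9.

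The table held 36353 such pairs, formed by 4429 promoters and 33334 distinct fragments with a median length of 2938 bp. Scores were whole numbers from 2 to 13683, and 84.7% of the cells held no score. Of the fragments, 11635 were listed in a single library and 0 in all 15, with 14 libraries as the most for any fragment. Fragments listed per library averaged 4213 ± 931 in Basal (SD, n = 3), 4576 ± 2118 in Early (SD, n = 4), 5160 ± 2352 in Late (SD, n = 4) and 5229 ± 5831 in Reactivated (SD, n = 4). Reactivated libraries 1 and 2 listed 32 and 335 fragments, whereas Reactivated libraries 3 and 4 listed 10035 and 10514. The sum of scores ran from 3097 in Reactivated library 1 to 8218430 in Reactivated library 4. The read depth of the libraries is not given in the sources used here, and the number of libraries limits the precision of each value.

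**Figure D1:**
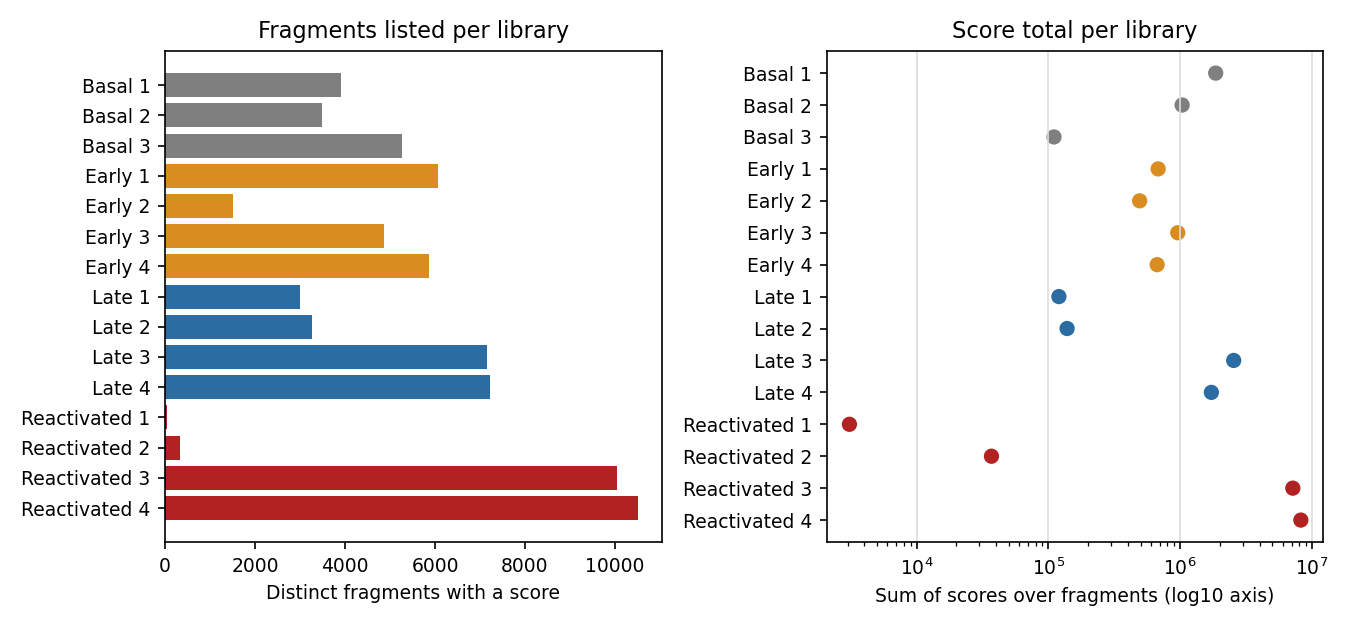
The left panel gives the number of distinct fragments with a score in each of the 15 libraries as bars that start at 0, and the right panel gives the sum of scores per library as points on a log10 axis, coloured by group. Reactivated libraries 1 and 2 listed 32 and 335 fragments and Reactivated library 4 listed 10514.

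Libraries of a group differed in how many fragments they shared. In 6 pairs of libraries (Basal 1 and 2, Early 3 and 4, Late 1 and 2, Late 3 and 4, Reactivated 1 and 2, Reactivated 3 and 4) the smaller library shared between 48.3% and 100% of its fragments with the larger, and the fragments listed by both made up 9.55% to 87.7% of those listed by either. The other 15 pairs within a group shared at most 16.7%, and the 84 pairs of libraries from different groups at most 29.7%. The 15 libraries thus form 9 sets, 2 in Basal, 3 in Early, 2 in Late and 2 in Reactivated, and counts are given below also with each set entered as a single mean. Between sets, the mean overlap was taken relative to independent placement over the listed fragments. Fragments listed in no set do not enter, which lowers this ratio within and across groups alike. A ratio below 1 thus does not show less sharing than by chance. The ratio was 0.668 within groups and 0.806 across groups, with an exact two-sided permutation p of 0.151 over 7560 assignments of sets to groups. The result depended on the measure: without the set of Reactivated libraries 1 and 2, this ratio was 0.708 within and 0.741 across groups (exact permutation p 0.767), whereas the Jaccard index was 4.63% within and 6.44% across (exact permutation p 0.0167, adjusted 0.1 over 6 such tests). With all sets the Jaccard index was 3.93% within and 5.15% across, with an exact permutation p of 0.110.

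**Figure D2:**
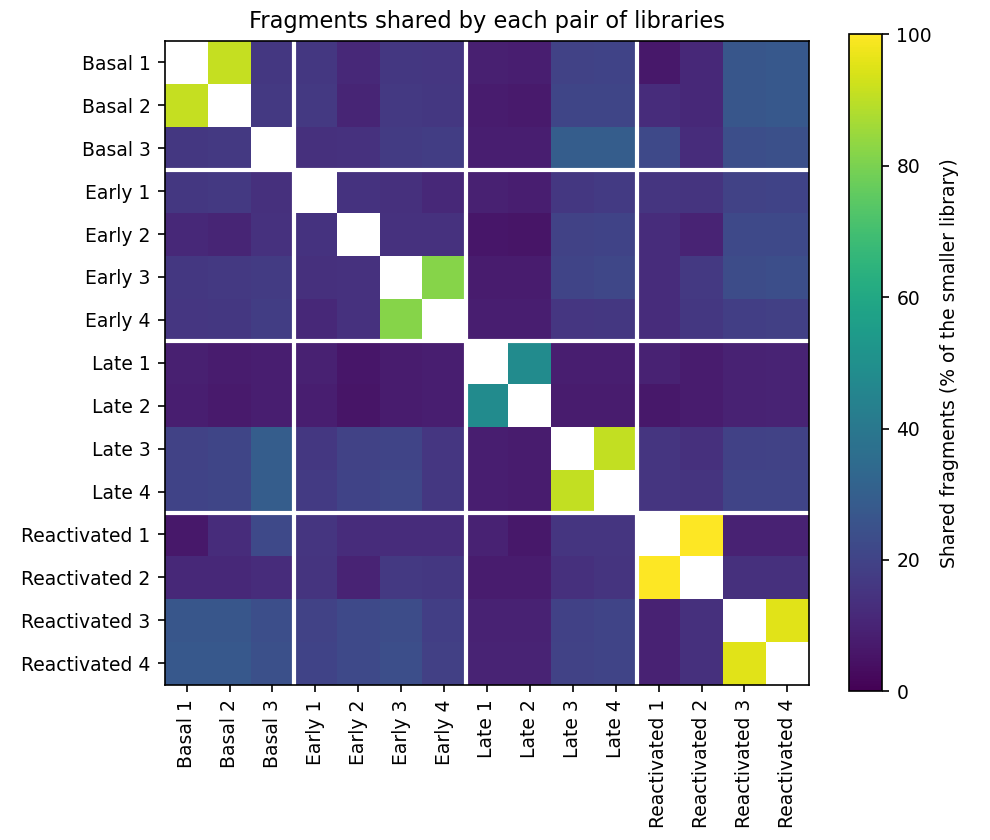
Each cell gives the fragments shared by the 2 libraries of its line and column, as a percentage of the fragments of the smaller library, on a colour scale from 0 to 100%, with white lines between the groups. The 6 bright pairs next to the diagonal shared 48.3% to 100% and every other pair of libraries at most 29.7%.

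At a score of 5 or more in at least 1 library, 9856 interactions were called in Basal, 14496 in Early, 13367 in Late and 12289 in Reactivated. Per promoter with at least 1 call this made 3.12, 3.99, 3.51 and 3.38 interactions. Of the called interactions, 33.0% in Basal, 52.0% in Early, 51.2% in Late and 51.4% in Reactivated were called in that group and in no other. The Basal count was 4863 without Basal library 3, and the Early count was 8724 without Early library 1. Crebzf, which encodes a bZIP transcription factor, had 163 listed fragments against a median of 6 per promoter, and 139 of them had a score in Reactivated library 2. The 16 fragments scored in 12 or more libraries included those of Zfp687, Kcna1, which encodes a voltage-gated potassium channel, and Trim28, which encodes a transcriptional corepressor. Each of these 3 fragments was scored in 14 libraries and in all 9 sets.

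Early against Basal concerns, by the group names, the earliest stage after conditioning. A fragment on chromosome 8 from 119468235 to 119468601, scored with the promoter of Atmin, which encodes a partner of the DNA damage kinase ATM, had scores of 1129 to 1921 in the 4 Early libraries and was listed at 0 in the 3 Basal libraries. Fragments of Pcdh11x, a protocadherin gene, Skp1a, a ubiquitin ligase subunit gene, Adam29, Ubfd1 and Rhobtb3 likewise had a score in every Early library and in no Basal library. The reverse was seen for a fragment of Dynlrb1, a dynein light chain gene, on chromosome 2 from 155210674 to 155214524, with scores of 3546, 2303 and 27 in Basal and 0 in all Early libraries. Fragments of Klf13, Arfgef1, AW549877, Ppp1r9b, which encodes the dendritic spine scaffold spinophilin, and Camk1d, a calcium/calmodulin-dependent kinase gene, had a score in every Basal library and in no Early library. Each fragment named for this comparison was also scored in Late or Reactivated libraries. The Atmin fragment had 3848 and 2624 in Late libraries 3 and 4, and that of Dynlrb1 had 264 and 393 in Reactivated libraries 3 and 4.

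None of these differences between Early and Basal passed the test. In simulated data with scores drawn from each library, the same test recovered 0 of 200 changed listings in every comparison. A listing that did not pass is thus no evidence of equal contacts, here and in the comparisons below. On the asinh scale the Atmin fragment had a mean of 7.87 ± 0.257 (SD, n = 4) in Early against 0 in Basal, a difference of 7.87 with a standard error of 2.93 and a limma adjusted p of 0.231. The other 5 fragments with scores in Early alone of the pair of groups differed by 6.86 to 7.64, with adjusted p from 0.216 to 0.416. The Dynlrb1 fragment differed by -7.10 with a standard error of 2.36 and an adjusted p of 0.185, and the Klf13, Arfgef1, AW549877, Ppp1r9b and Camk1d fragments by -6.98 to -6.76 with adjusted p from 0.185 to 0.416. By limma, 0 of 36353 listings passed in either direction, and 3868 had an unadjusted p under 0.05, against 1818 by chance if the libraries were independent. Of 35 splits of these 7 libraries, 7 gave at least as many, the real grouping among them. Limma on the mean score of each promoter gave 0 of 4429 promoters, with 258 at an unadjusted p under 0.05, and limma on the called interactions of each promoter gave 0 of 4403, with 201.

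Among single promoters, Phlpp1, a phosphatase gene, had 13 ± 6.16 called interactions in Early (SD, n = 4) against 5 ± 1.73 in Basal (SD, n = 3). Gcc2, Nr3c2, the mineralocorticoid receptor gene, and Rspo2 also had more in Early, with means of 5.5 to 11.25 in Early and of 0.667 to 5 in Basal. Crebzf had 10.0 ± 4.90 in Early against 19 ± 2 in Basal, and Krtcap2, Dock10, Grik4 and Arfgap3 had means of 0.25 to 5.25 in Early and of 4 to 9.33 in Basal. Their adjusted p lay between 0.740 and 1.

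Of the immediate early and activity-regulated genes, 20 of 47 had a promoter in the table, and 9 had a higher and 10 a lower mean score in Early than in Basal. Junb had 5.5 ± 0.577 called interactions in Early against 3.33 ± 2.31 in Basal, and Npas4, an activity-dependent transcription factor gene, had 4 ± 1.41 against 2.33 ± 0.577. Ier5 had 4.25 ± 3.20 against 6.33 ± 4.51, a difference of -2.08 that became 0.25 without Basal library 3. Maff, a small Maf transcription factor gene, had 2 called interactions in each Basal library and 0 in each Early library. Its mean score was lower in Early at the threshold adjusted over the list alone, the only member of the list to pass, whereas 0 members passed over all promoters tested. With each library set entered as its mean, its p adjusted over the list alone by limma was 0.168. Of the ionotropic and metabotropic glutamate receptors, 25 of 31 were measured, with 9 higher and 14 lower. Grm8 had 4.25 ± 2.75 called interactions in Early against 2.33 ± 4.04 in Basal, Grik4 had 1.75 ± 1.71 against 5.67 ± 3.79, and Grin3a had 0.25 ± 0.5 against 1.67 ± 0.577. Of the chromatin regulators, 27 of 93 were measured, with 15 higher and 9 lower. The remodeller genes Chd2 and Chd7 had 3.5 ± 1 and 2.75 ± 1.5 in Early against 1 and 0.667 ± 0.577 in Basal, and Hdac4 and Yy1 had 2.5 ± 1 and 1 ± 1.41 against 3.67 ± 0.577 and 2. For the glutamate receptors and the chromatin regulators, 0 members passed when adjusted over the list alone. Each of these 3 lists had a camera adjusted p of 0.913, and of 0.968 with an estimated correlation.

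The counts of this comparison depended on single libraries. Without Basal library 3, 1416 listings and 66 promoters passed, but this leaves Basal libraries 1 and 2, a single library set. Without Reactivated library 1, Early library 2 and Early library 4, 6, 4 and 1 promoters passed. Without Reactivated libraries 1 and 2, an alternative chosen after seeing the data, 195 listings and 9 promoters passed, without the variance trend 142 and 3, and after quantile normalization 16 promoters, whereas with each library set entered as its mean 0 did.

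Late against Early compares, by the group names, a later stage with the earlier. With all libraries counted as independent, limma found higher mean scores in Late for 4 promoters. Tgm2, a transglutaminase gene, Vangl2, a planar cell polarity gene, Egfl6 and Pi15 had scores in all 4 Late libraries and in no Early library. The mean asinh score over the listed fragments of Tgm2 was 2.33 to 2.50 in the Late libraries and 0 in Early, a difference of 2.42 with a standard error of 0.415 and a limma adjusted p of 0.0224. Vangl2 and Egfl6 rose by 2.42 and 2.56, each with an adjusted p of 0.0339, and Pi15 rose by 1.99 with an adjusted p of 0.0485. These were 4 of 4429 promoters tested, with 0 lower and 308 at an unadjusted p under 0.05. None of the 4 passed with each library set entered as its mean. The limma adjusted p was then 0.651 for Egfl6 and 0.711 for Tgm2 and Vangl2.

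Among single fragments, those of Map3k12, a stress-activated neuronal kinase gene, on chromosome 15 from 102236303 to 102248932, and of Hepacam, a glial adhesion gene, on chromosome 9 from 37421784 to 37423073, had scores in all 4 Late libraries and in no Early library. The Hepacam fragment had scores of 116 to 716 in Late, a mean asinh score of 6.35 ± 0.897 (SD, n = 4), and was listed at 0 in the other 11 libraries, with a difference of 6.35, a standard error of 1.93 and an adjusted p of 0.276. Fragments of Col27a1, a collagen gene, Tmem109 (listed also with Tmem132a), Mrpl15, a mitochondrial ribosomal protein gene, and Pea15a differed by 6.13 to 6.34. Fragments of Rhobtb3, Zhx1, Kpnb1, which encodes importin beta, Slc26a8, Atg10, an autophagy gene, and Mzt1 were scored in all 4 Early libraries and in no Late library, with differences of -6.86 to -6.05. The adjusted p of these 12 fragments lay between 0.276 and 0.279. By limma, 0 of 36353 listings passed and 5505 had an unadjusted p under 0.05, 3462 of them higher in Late.

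Arc, whose promoter drives the label, had 4 listed fragments, and each was scored in Late libraries alone. All but 1 of them had a single low score, of 7 and 5 in Late library 2 and of 2 in Late library 4. The median scores of Late libraries 1 to 4 were 18, 19, 160 and 100. The fragment on chromosome 15 from 74557103 to 74558248 had scores of 22, 20, 12 and 15 in Late libraries 1 to 4 and was listed at 0 in the other 11 libraries. Its mean asinh score was 3.51 ± 0.276 in Late (SD, n = 4), a difference of 3.51 from Early with a standard error of 1.45 and an adjusted p of 0.276. Arc had 1.5 ± 1 called interactions in Late (SD, n = 4) and 0 in Early, with an adjusted p of 0.0956.

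**Figure D3:**
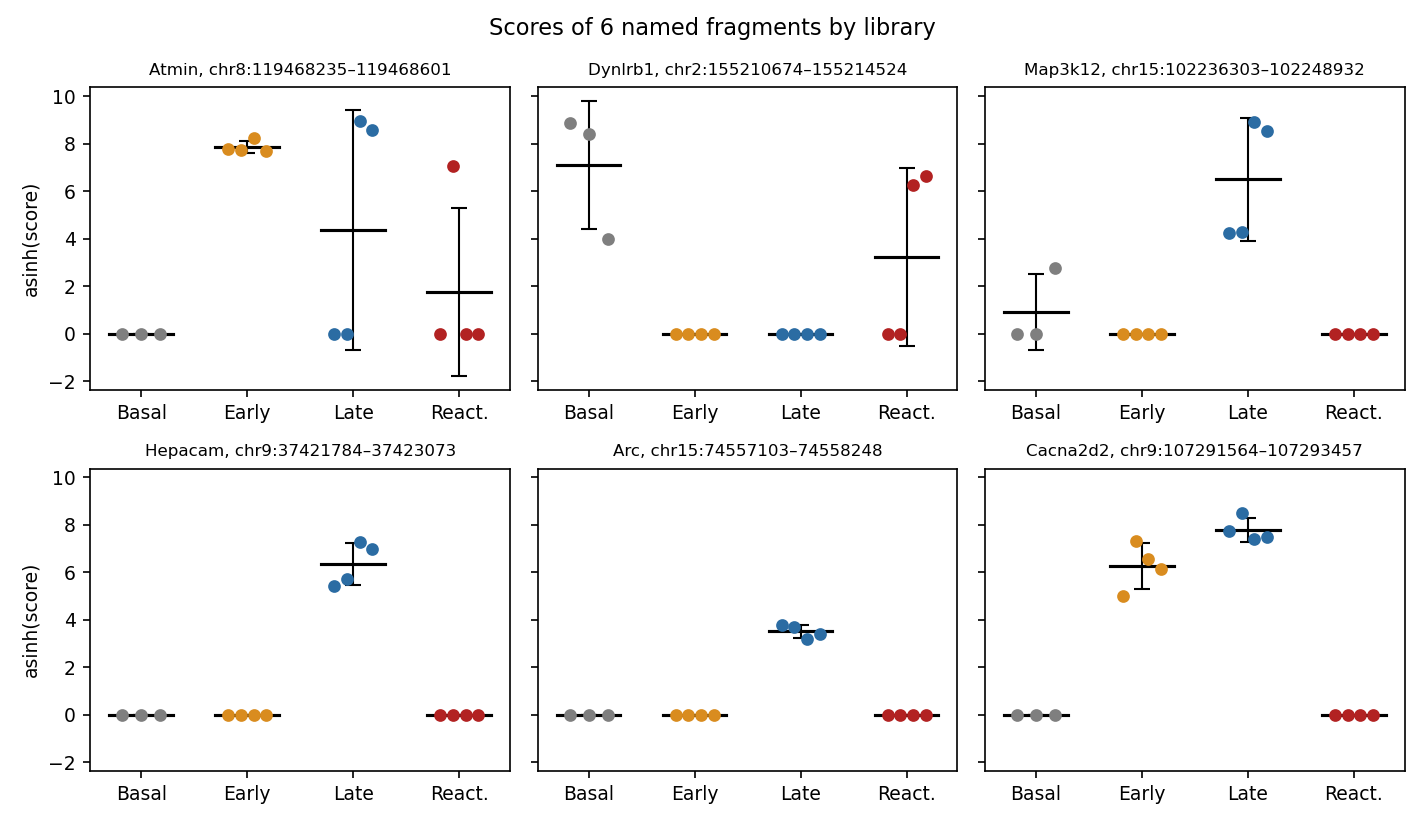
Points give the asinh score of 6 named fragments in each library by group, bars give the group mean, whiskers give 1 SD, and a fragment without a score is drawn at 0. The Hepacam and Arc fragments had scores in the 4 Late libraries alone, with means of 6.35 and 3.51, and the Dynlrb1 fragment had scores in Basal and in Reactivated libraries 3 and 4.

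Called interactions per promoter gave 0 of 4403 promoters by limma, with 420 at an unadjusted p under 0.05. Rnf20, a histone H2B ubiquitin ligase gene, had 6 called interactions in each Late library against 0.25 ± 0.5 in Early (SD, n = 4), with an adjusted p of 0.0956. Hlf, Tmem132a, Esco1, an acetyltransferase gene of the cohesin pathway, and Cul3 had means of 4 to 7.75 in Late and of 0.25 to 3.75 in Early. E2f6, Slc35a3, Dpp10, a potassium channel partner gene, Ppp4r2 and Sub1 had means of 1 to 3.75 in Late and of 4.75 to 9.25 in Early. The adjusted p of these 9 promoters lay between 0.306 and 0.857.

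Of the 20 immediate early and activity-regulated genes, 13 had a higher and 6 a lower mean score in Late than in Early. Nfil3, a bZIP repressor gene, had 4.25 ± 1.71 called interactions in Late against 1 ± 0.816 in Early, and Bdnf, the brain-derived neurotrophic factor gene, had 3.25 ± 2.87 against 1.5 ± 1. Npas4 had 1.25 ± 1.5 against 4 ± 1.41, and Junb had 3 ± 2.45 against 5.5 ± 0.577. Of the 25 glutamate receptor genes, 16 were higher and 6 lower. Grik4 had 4.5 ± 4.04 against 1.75 ± 1.71 and Grin3a 2.5 ± 1.91 against 0.25 ± 0.5. Cnih2 had 2.5 ± 1.73 against 3.25 ± 2.75, a difference of -0.75 that became 0.167 without Early library 3. Of the 27 chromatin regulators, 12 were higher and 13 lower. Smarcb1, a SWI/SNF subunit gene, had 2.5 ± 2.89 against 0, and the histone demethylase gene Kdm4b had 1.75 ± 0.957 against 0. Chd2 had 1.5 ± 0.577 against 3.5 ± 1, and the cohesin loader gene Nipbl had 0 against 2 ± 1.41. Camera placed the chromatin regulators below the other promoters. Their median was 0 and their mean 0.0159, against a median of 0.0620 over all promoters, and 11 of the 27 lay above that. In each of the 3 lists 0 members passed over all promoters and 0 when adjusted over the list alone, and the camera adjusted p was 0.860, or 0.998 with an estimated correlation.

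The 4 promoters depended on the treatment of paired libraries: with each library set entered as its mean, or as a random block, 0 passed, and the adjusted p of Tgm2 was 0.711 and 0.441. The count was 0 without Basal library 1 or 2, Early library 1, 3 or 4 or Reactivated library 3, 1 without Reactivated library 4 and on the log2 scale, 2 without Late library 3 or 4, 9 to 11 without Early library 2, Late library 1 or Late library 2, 13 without Reactivated libraries 1 and 2, which also brought 64 listings past the threshold, 10 with fragments listed with 1 promoter and 21 after quantile normalization; without the variance trend 57 listings passed. Pi15 did not pass without the variance trend, with an adjusted p of 0.0636 (range over alternatives 0.000504 to 1), nor without Basal library 3, Early library 2 or Reactivated library 1 or 2.

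Reactivated against Late addresses, by the group names, recall of the memory. The promoters of Tgm2, Vangl2 and Egfl6, which had scores in all 4 Late libraries, had none in any Reactivated library. Their mean asinh scores fell by 2.42, 2.42 and 2.56, with limma adjusted p of 0.0224, 0.0339 and 0.0339. These were 3 of 4429 promoters tested, with 0 higher and 613 at an unadjusted p under 0.05. None of the 3 passed with each library set entered as its mean. The limma adjusted p was then 0.407 for Egfl6 and 0.440 for Tgm2 and Vangl2. As stated above, Reactivated libraries 1 and 2 listed 32 and 335 fragments, so that a score of 0 in them is the usual value for any fragment.

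A fragment of Cacna2d2, a calcium channel subunit gene, on chromosome 9 from 107291564 to 107293457, had scores of 810 to 2455 in Late and was listed at 0 in all 4 Reactivated libraries. It differed by -7.79 with a standard error of 2.72 and an adjusted p of 0.141. Fragments of Setd3, a methyltransferase gene, Map3k12 and Hepacam were likewise scored in every Late library and in no Reactivated library, and the Cldn12 fragment, of a claudin gene, was scored in all Late libraries and, at 1000, in Reactivated library 2. These 4 differed by -7.25 to -6.35 with adjusted p from 0.141 to 0.219. The fragment of Otof, which encodes the calcium sensor otoferlin, on chromosome 5 from 30939784 to 30945354, had scores of 59 to 199 in the 4 Reactivated libraries and 0 in Late, a mean asinh score of 5.22 ± 0.532 (SD, n = 4). Fragments of Zfp949, Ide, which encodes the insulin-degrading enzyme, Mapk15 (listed also with Rbfox2 and Zfp251) and Ly96, which encodes a Toll-like receptor partner, were scored in Reactivated libraries 2, 3 and 4, and that of Atp6v1g1, a proton pump subunit gene, in libraries 3 and 4. These 6 fragments differed by 4.97 to 5.40, each with an adjusted p of 0.141. By limma, 0 of 36353 listings passed and 9507 had an unadjusted p under 0.05, 5876 of them higher in Reactivated.

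Called interactions per promoter gave 0 of 4403 promoters by limma, with 634 at an unadjusted p under 0.05. Crebzf had 16 ± 17.4 in Reactivated (SD, n = 4) against 10.25 ± 1.71 in Late (SD, n = 4), with 42 of them in Reactivated library 2; the difference of 5.75 became -2.92 without that library. Spock2, Dpp10, Krtcap2 and Ranbp6 had 12 to 17 called interactions in each of Reactivated libraries 3 and 4, 0 in libraries 1 and 2, and means of 1 to 3.5 in Late. Cacna2d1, a calcium channel subunit gene, had 7.5 ± 8.66 in Reactivated against 13 ± 7.53 in Late, a difference of -5.5 that became 2 without Reactivated libraries 1 and 2. Rbfa, Arfgef1, Cldn12 and Nfil3 had means of 0 to 4 in Reactivated and of 4.25 to 9.25 in Late, and without the same libraries the differences of Rbfa and Arfgef1 were both -1.25. The adjusted p of these 10 promoters lay between 0.0736, for Nfil3, and 0.962.

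Of the 20 immediate early and activity-regulated genes, 12 had a higher and 8 a lower mean score in Reactivated than in Late. Arc and Nfil3 fell at the threshold adjusted over the list alone, and 0 members passed over all promoters tested; with each library set entered as its mean, the limma p adjusted over the list alone was 0.725 for both. Arc had 0 called interactions in Reactivated against 1.5 ± 1 in Late, and Nfil3 had 0 against 4.25 ± 1.71. Sik1, a salt-inducible kinase gene, had 2.5 ± 2.89 against 0.25 ± 0.5, and Bdnf had 1 ± 1.15 against 3.25 ± 2.87. Homer1, a postsynaptic scaffold gene, had 5 ± 5.23 against 3.5 ± 3.51, a difference of 1.5 that became -0.167 without Reactivated library 4. Of the 25 glutamate receptor genes, 16 were higher and 8 lower. Grin1 and Grm2 had 2.5 ± 2.89 and 2.25 ± 2.63 in Reactivated against 0.75 ± 0.5 for both in Late, and Grm8 had 2 ± 2.31 against 4 ± 3.46, means that were equal without Reactivated libraries 1 and 2. Of the 27 chromatin regulators, 16 were higher and 11 lower. Nipbl had 2.5 ± 2.89 against 0 and Setd1a 2.75 ± 3.20 against 0.5 ± 0.577, whereas Kdm3a had 0.5 ± 0.577 against 1.75 ± 0.957 and Chd7 1.25 ± 1.5 against 2.5 ± 2.89, the latter also equal without these libraries. For these lists 0 members of the glutamate receptors and chromatin regulators passed when adjusted over the list alone. The camera adjusted p was 0.702 for the activity-regulated genes and the chromatin regulators and 0.771 for the glutamate receptors, or 0.992 with an estimated correlation for each. For the activity-regulated genes the median difference was 0.0992, above 0, while camera placed the list below the other promoters; the median over all promoters was 0.181, and 7 of the 20 activity-regulated genes, 12 of the 25 glutamate receptor genes and 16 of the 27 chromatin regulators lay above it.

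Without Reactivated library 1, 4895 listings and 155 promoters passed, without Reactivated library 2, 4898 and 147, and without both 9131 listings, 9028 of them higher in Reactivated, and 1940 promoters; with each library set entered as its mean 0 listings and 0 promoters passed. The count of 3 promoters became 0 with the set as a random block and without Basal library 1 or 2, Early library 1, 3 or 4 or Reactivated library 3 or 4, 1 without Early library 2 and on the log2 scale, 10 and 9 without Late library 1 and 2, 11 with fragments listed with 1 promoter and 25 after quantile normalization, and 59 listings and 5 promoters passed without the variance trend. Vangl2 and Egfl6 did not pass without Late library 3 or 4, where 2 promoters passed, Tgm2 among them.

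The other 3 comparisons pair the remaining groups. In Late against Basal, Tgm2 rose by 2.42 with an adjusted p of 0.0330, Dclre1c, which encodes the DNA repair nuclease Artemis, fell by 5.87 with an adjusted p of 0.0330, and Maff fell by 2.29 with an adjusted p of 0.0335, out of 4429 promoters with 363 at an unadjusted p under 0.05. None of them passed with each library set entered as its mean, where the limma adjusted p was 0.496 for Dclre1c and 0.969 for Tgm2. Dclre1c had 1 listed fragment, on chromosome 2 from 125128101 to 125133012, so that its promoter mean is the score of that fragment, and in the test of single listings the fragment had an adjusted p of 0.182. It had asinh scores of 7.28, 6.79 and 3.53 in the Basal libraries, 0 in all Late libraries and 3.33 in Early library 4. Maff was the only promoter of the activity-regulated genes to pass, over all promoters and when adjusted over the list alone, and without the variance trend its adjusted p was 0.0526 (range over alternatives 0.00011 to 1). In Reactivated against Basal, the same fragment of Dclre1c fell by 5.87 with an adjusted p of 0.0337 among promoters and of 0.181 among listings, with 497 promoters at an unadjusted p under 0.05. In Reactivated against Early, 0 of 4429 promoters passed by limma, with 499 at an unadjusted p under 0.05. Limma on single listings gave 0 in each of the 3, with 4698, 7362 and 7743 at an unadjusted p under 0.05, and limma on called interactions per promoter gave 0 in each, with 373, 391 and 473.

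By called interactions, Cacna2d1, Rbfa and Kcnq5, a potassium channel gene, had means of 6.25 to 13 in Late against 0.667 to 5.33 in Basal, and Crebzf, Krtcap2 and Relb, a gene of the NF-kappaB family, had 2.5 to 10.25 against 8 to 19. Nr3c2, Rpl21 and Spock2 had 7 to 9.25 in Reactivated against 0.667 to 1.33 in Basal, and Arfgef1, Rnf139 and Slc16a11 had 0.5 to 3.5 against 5 to 10.3. Crebzf, Ranbp6 and Rpl21 had 6.75 to 16 in Reactivated against 1.25 to 10.0 in Early, and Gcc2, Phlpp1 and Fgf18 had 0.5 to 7.25 against 5 to 13. Without Reactivated libraries 1 and 2 the difference of Crebzf from Early turned from 6 to -1.5 and that of Phlpp1 from -5.75 to 1. With each library set entered as its mean, 0 promoters passed in the 3 comparisons. Without Basal library 3, which leaves a single library set in Basal, 1505 listings and 68 promoters passed in Late against Basal. In Reactivated against Basal, 1591 and 61 then passed. The count of 3 promoters in Late against Basal became 0 without Basal library 1 or 2, Early library 1 or 3 or Late library 3, 1 without Early library 4, which was Dclre1c, 1 without Late library 4, which was none of the 3, 5 to 7 without any 1 Reactivated library, and 13 and 11 without Late libraries 1 and 2. The promoter of Reactivated against Basal was lost without Basal library 1 or 2, Early library 1, 2 or 3, Late library 2, 3 or 4 or Reactivated library 3 or 4, and the count was 2 without Late library 1 or Reactivated library 2 and 3 without Reactivated library 1. In Reactivated against Early 5, 125 and 135 promoters passed without Early library 2, Reactivated library 1 and Reactivated library 2. Without Reactivated library 1 or 2, 3948 and 4160 listings passed in Reactivated against Basal and 4631 and 4657 in Reactivated against Early.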

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

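The tests of explanations and of other groupings of the libraries in this part were chosen after the results were seen.

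The first pattern is that in 6 pairs of libraries of a group the smaller library shared 48.3% to 100% of its fragments with the larger, more than in any other pair. Identical values entered under 2 names are argued against, since at most 87.7% of the fragments listed by either library of a pair were listed by both. Biology of the group was not tested by the gap to the other pairs, since the rule of at least 40% sharing fixed that the others share less. High sharing did not extend to all pairs of a group, though. The other pairs of the same group shared at most 16.7% of their fragments, against at least 48.3% in the 6 pairs. What stays open is that each pair comes from a repeat preparation or sequencing of a sample: the lowest correlation of log2 scores over shared fragments was 0.912 in 5 of the 6 pairs, against at most 0.608 in other pairs, computed only for pairs with 50 or more shared fragments, which leaves out Reactivated 1 and 2. A single library entered under 2 names also stays open: in the same 5 pairs the chi-square of the scores per degree of freedom was at least 2.72, but a noise level of 1 holds only if scores are read counts, which no source states, and if either holds, the 15 libraries would amount to 9 independent samples.

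The second pattern is that Reactivated libraries 1 and 2 listed 32 and 335 fragments. Recall of the memory is argued against as the whole cause, since Reactivated library 3, from the same group, listed 10035, more than the 7224 of the Late library with most. A low yield of these 2 libraries stays open: all 32 fragments of library 1 were in library 2, at a median percentile of 77.8 of its scores, as a thinner sample of the same material would give. Crebzf had 139 listings in library 2, against 8 and 10 in Reactivated libraries 3 and 4. Whether a low yield would give so many was not tested. Libraries 1 and 2 form a library set, so a difference in the animals or in the preparation cannot be separated by these data.

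The third pattern is that fragments listed with several promoters carried the same score in each listing. Promoters lying on the same baited fragment are argued against, since promoters sharing a fragment had a median of 6.25% of their fragments in common. Scores that belong to a fragment and were copied to each of its promoters stay open as a source. Among promoters sharing under 50% of their fragments, 3624 of 3625 shared listings, or 99.97%, were identical. These were 2986 of the 2992 pairs of promoters sharing a fragment. The share therefore restates the pattern and does not test its source. No biological explanation was tested for this pattern. Under it, a score named here for Mapk15, Rbfox2 and Zfp251 together could belong to any of these promoters.

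Of 176 groups of 4 libraries examined, 19 (10.8%) held a library far from the other 3, with a gap to the nearest above Dixon's critical value for 4 samples. Chance gives about 5% for continuous normal values, but in 14 of the 19 the other 3 libraries had equal values, mostly small whole counts, so the share cannot be set against that figure. Early library 2 listed 1207 promoters, fewer than the other Early libraries. The Atmin fragment had a score of 1921 in Early library 3, above the other 3. The Cldn12 fragment had a score of 1000 in Reactivated library 2 and 0 in the other 3. Crebzf had 42 called interactions in Reactivated library 2, and Cldn12 had 1 there, against 0 in the other Reactivated libraries. In Early library 1, Ier5 had 9 called interactions, Bdnf 3, and Arfgap3, Grin3a, Rnf20 and Tmem132a 1 each, all above the other 3, and Chd2 had 2, below them. In Early library 2, Rspo2 had 3 and Hdac4 1, below the other 3. Krtcap2 had 2 in Late library 1, Sik1 had 1 in Late library 3, Grin1 had 0 in Late library 2, Grm2 had 0 in Late library 1 and Arc had 3 in Late library 2, each apart from the other 3 Late libraries.

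For each comparison, all 35 splits of its libraries into groups of the same sizes were tested. The real grouping is 1 of the 35 and is included in each count of splits. The splits move single libraries, so they can part the libraries of a set, which are not independent. For promoters, 2 of 35 splits gave at least the 4 of Late against Early, with 34 in the split that joins Late 1 and 2 with Early 1 and 2. In Reactivated against Late 3 of 35 splits gave at least 3, with a highest other of 2413, in Late against Basal 6 gave at least 3, with 48, and in Reactivated against Basal 10 gave at least 1, with 1694. Chance cannot be excluded for these 4 counts, and with each library set entered as its mean all of them were 0. The listings at an unadjusted p under 0.05 numbered 3868 in Early against Basal, where 7 of 35 splits gave as many (highest other 5159), 5505 in Late against Early, where 3 did (6320), and 9507 in Reactivated against Late, where 3 did (11891). They numbered 4698 in Late against Basal, where 9 splits gave as many (6823), 7362 in Reactivated against Basal, where 8 did (10180), and 7743 in Reactivated against Early, where 7 did (8963), so chance cannot be excluded for these counts either.

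For single listings and gene lists past the threshold in all 6 comparisons, and for promoters in Early against Basal and Reactivated against Early, the real count was 0, so that all 35 of 35 splits were as large by construction and nothing follows from them. The highest counts of another split were 944 listings in Reactivated against Late, 6476 in Reactivated against Basal and 0 in the other 4 comparisons, 1 gene list in Late against Early and 0 in the other 5, and 11 and 921 promoters. The splits with 944 and 6476 listings, and those with 921, 1694 and 2413 promoters, point to a structure of the samples. Each placed Reactivated libraries 1 and 2 on the same side, and no test separated the library sets from the few fragments of these libraries.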

How the results depend on the processing

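Settings fixed in advance were the call thresholds, the scale and normalization of scores, summaries per promoter, the replicate number as a block and leaving out each library; those on library sets, the variance trend, Reactivated libraries 1 and 2 and fragments listed with 1 promoter were chosen after seeing the data, as were all settings for promoters. Of 192 values for single listings 171 stayed at 0, of 144 for gene lists 141 did, of 35 group counts 33 stayed within 1.5 times, and of 138 promoter counts 48 did. For single listings, limma with the variance trend recovered 0 of 200 simulated changes at the spread found. A listing count that stayed at 0 is therefore no sign of stability. For named fragments, 521 of 540 values with a library left out and 121 of 144 under other settings stayed on their side of the threshold, 19 and 23 passed it, and 0 turned direction. All but the Cldn12 fragment had no score in any library of a compared group, so leaving out a library could not turn them. The lack of turns is therefore no sign of stability. For called interactions of named promoters, 27 of 1215 values with a library left out and 21 of 405 under other settings passed it. Where a cause is not given the cause was not tested, and the few libraries and the many empty cells limit every count.

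Comparisons are listed in the order Early against Basal, Late against Early, Reactivated against Late, Late against Basal, Reactivated against Basal, Reactivated against Early. Without the variance trend, 142, 57, 59, 201, 146 and 5 listings passed, a setting that also called listings in simulated data with no change. Without Reactivated libraries 1 and 2 there were 195, 64, 9131, 236, 9057 and 9150, which leaves a single library set in Reactivated. With each library left out in turn the listings ranged from 0 to 1416, 0 to 0, 0 to 4898, 0 to 1505, 0 to 4160 and 0 to 4657. The values of 1416, 1505 and, in Reactivated against Basal, 1591 were those without Basal library 3, which leaves a single library set in Basal. All other values above 0 were those without Reactivated library 1 or 2. With the replicate number as a block, 0 listings passed in each comparison. Called interactions ranged from 4863 to 9580 in Basal, 8724 to 13863 in Early, 11430 to 12866 in Late and 11274 to 12289 in Reactivated.

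For promoters, reported as 0, 4, 3, 3, 1 and 0, the counts with each library set as its mean, and with the set as a random block, were 0 in all comparisons. Quantile normalization gave 16, 21, 25, 34 and 19 in the 5 comparisons before the last. The log2 scale gave 1 in Late against Early and 1 in Reactivated against Late. No variance trend gave 3 in Early against Basal, 5 in Reactivated against Late, 2 in Reactivated against Basal and 1 in Reactivated against Early. The replicate number as a block gave 5 in Reactivated against Late and 0 in Reactivated against Basal, and the adjusted p of Maff in Late against Basal became 0.0621 (range over alternatives 0.00011 to 1). Without Reactivated libraries 1 and 2 the counts were 9, 13, 1940, 23, 2018 and 1990. Fragments listed with 1 promoter gave 10 in Late against Early, 11 in Reactivated against Late, 15 in Late against Basal and 5 in Reactivated against Basal. With each library left out, the counts ranged from 0 to 66, 0 to 11, 0 to 155, 0 to 68, 0 to 61 and 0 to 135.

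For gene lists, 1 list, the microglia and immune markers, passed on the highest score of each promoter in Reactivated vs Late (adjusted p 0.0498, range over alternatives 0.0498 to 0.992) and on the mean of each library set in Reactivated vs Basal (0.0398, range 0.0398 to 0.965) and in Reactivated vs Early (0.0433, range 0.0433 to 0.956). On mean scores with an estimated correlation, its camera adjusted p was 0.992, 0.965 and 0.956 in these comparisons. Only 3 of its 26 genes were measured. Of these, Cx3cr1 and Tyrobp were scored in Reactivated libraries 3 and 4 alone, which form 1 library set. With each library left out, the count of lists was 0 to 0 in every comparison.

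Differences in called interactions turned direction for 7 results, in 11 combinations of result and setting. For Crebzf they became -2.25 in Reactivated against Late and -1.5 in Reactivated against Early at a threshold of 10, -1.75 and -1.5 without Reactivated libraries 1 and 2, and -2.92 and -2.67 without library 2, in ranges over single libraries left out of -2.92 to 9.42 and -2.67 to 9.67. Without Reactivated libraries 1 and 2, Cacna2d1 became 2 in Reactivated against Late and Phlpp1 became 1 in Reactivated against Early. Ier5 became 0.25 in Early against Basal without Basal library 3 (range -4.25 to 0.25). In Late against Early Cnih2 became 0.167 without Early library 3 (range -1.83 to 0.167). Homer1 became -0.167 in Reactivated against Late without Reactivated library 4 (range -0.167 to 3.17). The limit of 1 Mb, the exclusion of contacts between baited fragments and the median distance were not run, since bait positions are not in the table used here, nor was the margin between thresholds, which was written for pooled columns.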

Other observations

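The tests of hypotheses in this part were chosen after the results were seen; the 20 gene lists and the camera test on them were not. Contacts of other gene groups are given here for the comparison in which each was examined, as mean scores per promoter and called interactions per promoter. In Late against Early, the synaptic vesicle and exocytosis genes had 20 of 28 members higher in Late and 7 lower. Slc17a6, which encodes a vesicular glutamate transporter, had 5 called interactions in each of Late libraries 1 and 2 and 0 in all Early libraries, and Napb, a membrane fusion gene, had 0.75 ± 0.957 in Late against 4 ± 3.56 in Early. Of the synaptic adhesion and axon guidance genes 21 of 38 were higher and 14 lower, with Cadm3 at 5.5 ± 3.51 against 2.25 ± 1.5 and Slit2 at 1.25 ± 0.5 against 2.75 ± 2.06. The voltage-gated ion channels had 16 of 27 higher and 10 lower, with Kcnq5 at 6.25 ± 6.70 against 2.5 ± 1.73 and Dpp10 at 1 ± 1.15 against 5.25 ± 2.22. The GABA receptors and GABA synapse genes had 6 of 11 higher and 5 lower, with Slc6a11 at 0.5 ± 1 against 1.5 ± 1. The postsynaptic scaffold and signalling genes had 6 of 14 higher and 8 lower, with Camk4 at 3.75 ± 2.63 against 2.5 ± 1.91 and Homer3 at 0.5 ± 0.577 against 1.75 ± 1.26. The median difference over all promoters was 0.0620, and 17 of 28 vesicle, 18 of 38 adhesion, 16 of 27 channel, 6 of 11 GABA and 5 of 14 postsynaptic genes lay above it. Camera placed the adhesion and GABA lists below the other promoters. The adhesion median of 0.0401 lay below that of all promoters, whereas the GABA median of 0.0917 lay above it. Camera gave an adjusted p of 0.860 for the vesicle, GABA and postsynaptic lists, 0.869 for the adhesion list and 0.893 for the channels, and of 0.998 for each with an estimated correlation.

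In Early against Basal, the translation factors and ribosomal proteins had 27 of 51 members higher in Early and 22 lower, with Rpl36 at 2 ± 0.816 called interactions against 0.333 ± 0.577 and Eif3b at 1 ± 0.816 against 3.33 ± 2.31. The neuronal RNA-binding and mRNA transport genes had 10 of 22 higher and 10 lower, with Elavl1 at 1 ± 0.816 against 0 and Rbfox2 at 2.25 ± 0.5 against 3.67 ± 0.577. The cAMP, MAPK and CREB signalling genes had 18 of 37 higher and 14 lower, with Mapk9, which encodes a Jun kinase, at 4 ± 2.16 against 0 and Rap1b at 0 against 1 ± 1. The neurotrophin and growth factor genes had 12 of 23 higher and 7 lower, with Egfr at 2.25 ± 1.5 against 0 and Vegfa at 0.25 ± 0.5 against 1.33 ± 1.53. The cytoskeleton and axonal transport genes had 13 of 27 higher and 11 lower, and Nefh, a neurofilament gene, and Rock1, a kinase gene, passed the threshold adjusted over the list alone, while 0 members passed over all promoters. Both were scored in Basal libraries 1 and 2 alone, which form 1 library set, and with each set entered as its mean, an alternative chosen after seeing the data, the p adjusted over the list alone was 0.0362 for Nefh and 0.0502 for Rock1. Nefh had 0 called interactions in Early against 1.33 ± 1.15 in Basal. The housekeeping and mitochondrial energy genes had 13 of 23 higher and 10 lower, with Sdha at 1.25 ± 0.957 against 0 and Ywhaz at 0 against 2.67 ± 2.31. Each of these 6 lists had a camera adjusted p of 0.913, and of 0.968 with an estimated correlation. Camera placed the translation, cAMP and housekeeping lists below the other promoters, although their medians were 0.0221, 0 and 0.0843.

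In Reactivated against Late, markers of hippocampal cell types were examined, as contacts and not as expression, in nuclei sorted for a neuronal protein. The median difference over all promoters was 0.181, so a member can be higher in Reactivated and still lie below most promoters. The dentate and pyramidal neuron markers had 18 of 23 members higher in Reactivated and 5 lower, with 14 above that median, and Wfs1 was at 4 ± 4.62 called interactions against 1.75 ± 2.06 and Spock1 at 1 ± 1.15 against 4.25 ± 4.35. The interneuron markers had 10 of 17 higher and 7 lower, with 8 above the median, and Sst was at 3.25 ± 3.77 against 1 ± 0.816 and Gad1 at 0.75 ± 0.957 against 2.25 ± 1.5. The astrocyte markers had 10 of 13 higher, all above the median, and 3 lower, with Aldh1l1 at 1.5 ± 1.73 against 0.25 ± 0.5, and the oligodendrocyte lineage markers had 8 of 13 higher, all above the median, and 4 lower, with Sox10 at 1.75 ± 2.06 against 0.25 ± 0.5. Of the microglia and immune markers 3 of 26 were measured: Cx3cr1 and Tyrobp, which passed the threshold adjusted over the list alone, had scores and called interactions in Reactivated libraries 3 and 4 alone, which form 1 library set, and Csf1r had 0.25 ± 0.5 against 3 ± 3.46. The endothelial and mural markers had 2 of 4 higher and 2 lower, with 1 above the median, and Flt1 was at 0.75 ± 0.5 against 2.25 ± 0.5. Camera gave an adjusted p of 0.831 for the interneuron markers, 0.984 for the oligodendrocyte markers and 0.702 for the other 4 lists, and of 0.992 for each with an estimated correlation. Camera placed the oligodendrocyte list below the other promoters, although its median was 0.326. Over all 6 comparisons 0 of 20 lists passed, and 2 results had an unadjusted camera p under 0.05, the synaptic vesicle genes in Late against Basal (p 0.0473, adjusted 0.556, and p 0.545 with an estimated correlation) and the astrocyte markers in Reactivated against Early (p 0.0432, adjusted 0.682, and p 0.487 with an estimated correlation).

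Fragments scored in every library of a group and in no other library numbered 84 in Basal, 3 in Early (those of Foxo3, Prrg4 and Dtx1), 44 in Late and 0 in Reactivated. Those in Late included fragments of Arc, Klf4 and Nfil3, with scores of 12 to 22, 15 to 76 and 10 to 43. The counts over every library cannot be compared between groups. Reactivated library 1 listed 32 fragments in all, which caps the Reactivated count. Basal required a score in 3 libraries from 2 sets, Late in 4 from 2 sets and Early in 4 from 3 sets. Counted by library sets, 117 fragments were in both Late sets and in no other, 108 in both Basal sets, 6 in all 3 Early sets and 11 in both Reactivated sets. An arbitrary choice of library sets could give as many. Of 36 choices of 2 sets, 20 gave at least the 117 of Late, the real choice among them, with a highest other of 744. For Basal this held for 22 of 36 choices, for Reactivated for 30 of 36 and for Early for 48 of 84 choices of 3 sets.

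A hypothesis was that activity-regulated promoters gain contacts in the Late group. Among 2000 promoters with fragments in each of the Late sets, the same or different ones, 119 had a fragment that both Late sets and no other set listed, and 3 of 8 activity-regulated promoters (Arc, Klf4 and Nfil3) were among them, where 0.476 would be expected. The one-sided Fisher exact p was 0.00923 and the adjusted p over 80 tests of lists and groups 0.738, so the result fails the correction and chance could account for it.

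Another hypothesis was that recurrent fragments mark short-range contacts. Of 442 promoters with fragments in 3 or more library sets and fragments in a single set, 384 had the recurrent ones closer together, with median spacings of 0.0864 Mb and 0.994 Mb. In 1000 shuffles within promoters the median count was 216 and the highest 247, a one-sided permutation p of 0.001, the smallest these shuffles can give. Spacing among fragments of a promoter stands in for the distance to the bait, whose position is not in the table used here, so the result is consistent with the hypothesis and does not test the distance itself.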
